A study of Mus musculus with 6 samples.

How the data were processed

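Gene expression was measured in the dorsal and lateral prostate lobes of 6 TRAMP mice, 3 given OSU-CG5 at 100 mg/kg per day and 3 given vehicle. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 2 ug by the standard Affymetrix protocol. The deposited values are log2 expression values per probe set, with RMA named in the submitters' processing notes. The software that ran RMA and its version are not given in the sources used here. As background, RMA fits background, quantile normalization and a probe summary over the arrays together, so the arrays share a distribution, and a broad shift of transcripts in 1 direction is partly removed. No raw probe intensities were used here. The deposited values covered 45101 probe sets, and without the 64 Affymetrix controls among them the log2 values ran from 1.76 to 14.5.

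Each array was assigned to a group by the treatment named in its tissue source label. The free-text description of some treated samples carries a different number after the compound's prefix, and the source label and title were followed. Replicate numbers only name the mice and pair none of them. The series design states that mice were randomised and that RNA came from 3 mice per group. No batch or scan date was used here.

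Probe sets were named from the platform's annotation, with symbols looked up in a RefSeq gene table by gene number. Of the 45037 probe sets left after removing 64 Affymetrix controls, 34945 had a single symbol, 932 had several and 9160 had none here. A gene number was found in the RefSeq table for 34741, and 0 symbols changed. Only probe sets with a single symbol were given a gene name. For gene lists each gene was represented by its probe set of highest mean over the 6 arrays, which gave 18193 genes. The 32 lists named 722 genes, of which 668 were measured. Of 10 genes that were to be reported whatever their values, 8 had a probe set with a single symbol, and the others were not analysed here.

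The test was limma's lmFit and eBayes on the deposited log2 values (limma 3.58.1, R 4.3.3), OSU-CG5 minus vehicle, with no filter and Benjamini-Hochberg adjustment over all 45037 probe sets at 0.05. A descriptive count used an unadjusted p under 0.01 and at least a 1.5-fold difference. SE is the moderated standard error of the log2 difference, and SD is that of the 3 arrays of a group. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists, and with camera at an estimated correlation and fry's directional test as alternatives. Each list's median was also set against 10000 random lists matched on mean expression. Single measures with 3 values per group were compared by two-sided exact permutation tests, whose smallest possible p is 0.1. Whether a pattern stayed without vehicle replicate 2 was judged by the 95% t interval of the group difference over the remaining arrays. The procedure was tested on simulated data for this comparison, with 200 of 45037 probe sets changed in each of 5 runs and independent noise. At an adjusted p under 0.05 it called 10.1% of those changed 1.5-fold, 84.2% of those changed 2-fold and 99.1% of those changed 4-fold. There were 56 false calls over 224185 unchanged probe sets, beside 34, 282 and 327 calls among those changed 1.5-fold, 2-fold and 4-fold. The false share of all calls was thus above 0.05. These shares hold for the simulated noise only and are not rates of detection for the real arrays. On the real arrays a probe set of Ubap2l with a 2.87-fold difference had a limma adjusted p of 0.112, and 0 probe sets passed.

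The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took, among probe sets with a single symbol, a group mean of at least log2 6 and no overlap between groups, the 12 largest rises and 12 largest falls past the adjusted threshold. As none passed, the places were filled with those of smallest unadjusted p and at least 1.5-fold. It added up to 4 members of each list with the smallest unadjusted p, some of which are described, and the fixed genes. Alternatives were a minimum mean of log2 6 or 4, arrays centred on their median, repeated quantile normalization, cyclic loess, an intensity trend with a robust prior, no moderation, array quality weights, 1 probe set per gene, and leaving out each array in turn. A test over probe sets with a single symbol only and families of genes sharing a symbol prefix, with at least 15 members, were added after the data were seen. For arrays, the number of arrays limits the precision, and depth has no count here.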

Results

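Prostates of TRAMP mice were compared after oral treatment with OSU-CG5 or vehicle. TRAMP mice carry the SV40 T antigens under a prostate-directed probasin promoter and develop prostate cancer with age. OSU-CG5 is a compound known here by its code name, described in earlier work as an energy restriction-mimetic agent. Intact males, crosses of C57BL/6 TRAMP with FvB, were dosed daily at 100 mg/kg for 4 weeks, from 6 to 10 weeks of age. RNA came from the microdissected dorsal and lateral lobes of 3 mice per group, taken 2 to 4 h after the last dose, and each mouse was measured on 1 Affymetrix array. The arrays held 45037 probe sets besides 64 controls, with array medians between 5.30 and 5.38 on the log2 scale. Precision was limited by the number of arrays, 3 per group.

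The arrays were not equally alike. Vehicle replicate 2 had Pearson correlations across probe sets of 0.966 to 0.981 with the other arrays, and every other pair lay between 0.987 and 0.995. On a principal component holding 60.4% of the variance it scored 85.6. Vehicle replicate 1 scored 15.2, vehicle replicate 3 -6.1 and the OSU-CG5 arrays -34.8 to -27.4. Transcripts of seminal vesicle secretions, a gland next to the prostate, were high in that sample. Svs5 read 9.69 there against 4.54 to 6.62 on the other arrays, and Svs4 read 9.65 there. The mean of 6 such transcripts was 7.91 in vehicle replicate 2, 5.08 in vehicle replicate 3 and 3.56 to 4.55 on the other 4 arrays. The median SD within a group was 0.18 for vehicle and 0.13 for OSU-CG5 (log2, n = 3 each). The 3' to 5' signal difference of Gapdh, a sign of RNA integrity, was 2.39 ± 0.32 in vehicle and 2.89 ± 0.16 with OSU-CG5 (SD, n = 3; two-sided exact permutation p = 0.2, where 0.1 is the smallest this design allows). For Actb it was 2.99 ± 0.13 and 3.03 ± 0.07 (n = 3; exact permutation p = 0.6).

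The comparison of OSU-CG5 with vehicle asked which transcripts of the dorsolateral prostate differed after treatment. Most probe sets past a descriptive threshold read higher with OSU-CG5, and many of these were secondary probe sets of their gene or had no single gene symbol. Transcripts of antigen presentation, extracellular matrix, muscle and vessels read lower, and cell cycle transcripts read higher, by less than 1.5-fold for most members. None of these list shifts held with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.669 or higher) or in fry's directional test. No single probe set passed the adjusted threshold with all 6 arrays. With limma and Benjamini-Hochberg adjustment, 0 of 45037 probe sets had an adjusted p under 0.05, and the smallest adjusted p was 0.112. At an unadjusted p under 0.05 there were 7399 probe sets, 4338 higher and 3061 lower, where 2251.85 would be expected by chance. An unadjusted p under 0.01 with at least a 1.5-fold difference held for 1420 probe sets, 1320 of them higher with OSU-CG5 and 100 lower. The groups did not overlap for 10648 probe sets, 23.6% of those tested, where chance gives 10%. An ordinary linear model without moderation and limma with an intensity trend and robust prior also gave 0 adjusted calls, and limma with array quality weights gave 822, of which 762 were higher and 60 lower. Without vehicle replicate 2 the adjusted count was 400 (379 higher, 21 lower) and without vehicle replicate 3 it was 885 (851 higher, 34 lower), while it stayed at 0 without any of the other 4 arrays. The unadjusted count was 3019 without vehicle replicate 3, 747 without OSU-CG5 replicate 2 and 895 without OSU-CG5 replicate 3.

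The 12 named genes with higher signal all stood apart from vehicle in every array, which the naming rule required. None passed adjustment with all arrays. A probe set of Ubap2l, an RNA-binding protein of stress granules, read 4.92 ± 0.27 in vehicle and 6.44 ± 0.12 with OSU-CG5 (log2, SD, n = 3), a 2.87-fold difference (log2 difference 1.52, SE 0.16; limma adjusted p = 0.112). Scap, the escort protein of the sterol-responsive SREBP factors, read 5.11 ± 0.15 and 6.21 ± 0.15, a log2 difference of 1.10 (SE 0.13). Log2 differences were 1.34 (SE 0.18) for the histone methyltransferase Nsd3, 0.89 (SE 0.13) for Mllt10 and 0.91 (SE 0.14) for the remodelling ATPase Srcap. Trp53bp1, which acts in repair of DNA double-strand breaks, differed by 1.15 (SE 0.17), and Lin54, a subunit of the DREAM complex, by 0.91 (SE 0.14). The clock gene Per3 differed by 1.20 (SE 0.18), and its brighter probe set by 0.56 (SE 0.17). Mcc, the ubiquitin ligase Arih2, Nav2 and E030024N20Rik differed by 1.0, 1.02, 0.96 and 1.13. Of these 12 genes, 11 had another probe set, and the brightest of these lay in the same direction for 8, with a median log2 difference of 0.26 against 1.02 for the named ones. For Mcc, Srcap and Nav2 it was -0.02, -0.07 and -0.25. For Ubap2l it was 0.29 (SE 0.13), while the gene's remaining probe sets differed by -0.17, -0.26, -0.05 and -0.42. For Scap it was 0.14 (SE 0.18), for Nsd3 0.34 (SE 0.11) and for Trp53bp1 0.26 (SE 0.13). All 12 named genes passed the adjusted threshold in limma without vehicle replicate 2, without vehicle replicate 3 and with array weights. These refits reused the arrays from which the genes were chosen, so they are no independent support. The other alternatives gave 0 adjusted calls.

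The 12 named genes with lower signal included several of immune, vessel and matrix cells. H2-Aa, a chain of the class II antigen-presenting complex, read 9.05 ± 0.11 in vehicle and 8.31 ± 0.17 with OSU-CG5 (log2, SD, n = 3), a log2 difference of -0.73 (SE 0.13; limma adjusted p = 0.136). C1qb, a complement chain made by macrophages, differed by -1.04 (SE 0.22), the collagen VI chain Col6a2 by -0.80 (SE 0.16) and Flt4, a receptor of lymphatic endothelium, by -0.73 (SE 0.14). Scp2, a sterol carrier, differed by -0.75 (SE 0.12), the acyl-CoA synthetase family member Acsf2 by -0.67 (SE 0.13), the dipeptidase Cndp2 by -0.70 (SE 0.13) and the mitochondrial carrier Slc25a39 by -0.66 (SE 0.13). Ppp1r11, an inhibitor of protein phosphatase 1, differed by -0.85 (SE 0.13), Wfdc6a by -0.79 and Cldnd1 by -0.70. A probe set annotated to the small nucleolar RNA gene Snord104 differed by -0.77, and which transcript it read was not tested. In limma 6 of these 12 passed the adjusted threshold without vehicle replicate 2, 5 without vehicle replicate 3 and 12 with array weights. Here too the refits reused the arrays from which the genes were chosen. The brightest other probe set lay in the same direction for 7 of the 9 genes that had 1, with a median of -0.36, and was 0.04 for Ppp1r11 and 0.08 for Scp2. The probe sets of Trp53bp1, H2-Aa, Slc25a39 and C1qb carry an identifier of a kind that can also bind related transcripts.

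**Figure D1:**
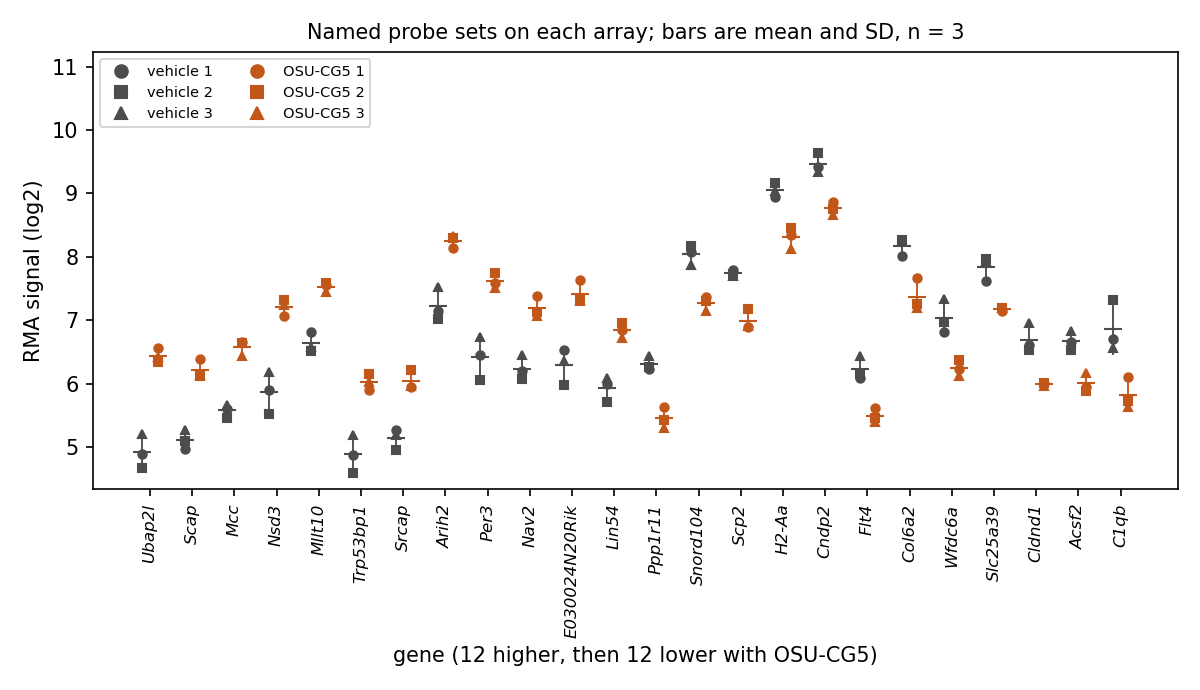
RMA signal on a log2 scale (vertical axis) for the 12 named genes higher and the 12 lower with OSU-CG5 (horizontal axis), with a point per array, shaped by replicate and coloured by group, and bars for the mean and SD (n = 3). The groups do not overlap for any of the 24 genes shown, a condition of the naming rule, and Ubap2l reads 4.92 in vehicle and 6.44 with OSU-CG5.

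Probe sets without a single gene symbol made up 56.2% of the higher ones at an unadjusted p under 0.01 and 1.5-fold (742 of 1320), 12% of the lower ones (12 of 100) and 22.4% of all those tested. Among probe sets with a mean of at least log2 6, the 2349 without a single symbol had a median log2 difference of 0.24, and 67.4% were above 0. The 15268 with a single symbol had a median of 0.00, and 49.4% were above 0. On single arrays the median of the unnamed minus that of the named probe sets was -0.29, -0.16 and -0.29 with OSU-CG5, -0.54 and -0.48 in vehicle replicates 1 and 3, and -1.07 in vehicle replicate 2. Of the 578 higher probe sets that had a single symbol, 428 (74.0%) were not the brightest of their gene, against 47.9% of all probe sets with a single symbol.

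Of 32 gene lists fixed before the data were examined, 9 differed from the other genes by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, 3 upward and 6 downward. Over all 18193 genes the median log2 difference was -0.09, and camera sets each list against that background. None of the 9 held with a correlation estimated for each list, where the smallest adjusted p was 0.669, and fry's directional test called 0 lists, with a smallest adjusted p of 0.189, while its test for change in either direction called 1. Estimated correlations in the 9 lists ran from 0.19 for fibroblasts and matrix to 0.38 for smooth muscle, against the preset 0.01. The preset treats such genes as nearly independent, so its p-values can be far too small. Ranges of list medians given below span all alternatives, each array left out in turn among them. No member of any list passed limma's adjusted threshold over all probe sets, so the counts given are those at an unadjusted p under 0.05 and those adjusted over the list alone. Of all tested probe sets 16.4% had an unadjusted p under 0.05. The 7 of 45 cell cycle genes and 3 of 25 unfolded protein response genes did not exceed that share, while the other called lists did.

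Cell cycle transcripts were called upward with the preset correlation. The 45 measured members had a median log2 difference of 0.13, 34 were above 0, and camera gave an adjusted p of 1.89e-06 (adjusted p = 0.669 with an estimated correlation). At an unadjusted p under 0.05, 7 were higher and 0 lower, and 2 passed when adjusted over the list alone. Top2a, a DNA topoisomerase of dividing cells, read 9.44 ± 0.06 in vehicle and 10.17 ± 0.15 with OSU-CG5 (log2, SD, n = 3). The log2 differences of the spindle kinesin Kif11, the kinetochore protein Ndc80 and the ribonucleotide reductase subunit Rrm1 were 0.60 (SE 0.13), 0.51 (SE 0.13) and 0.48 (SE 0.13). The proliferation marker Mki67 differed by 0.49 (SE 0.17; limma adjusted p = 0.228). Vehicle replicate 2 had a list mean of 8.06, as high as the OSU-CG5 arrays at 8.02 to 8.18, and the other vehicle arrays read 7.80 and 7.91. The list's median was 0.24 without vehicle replicate 2 and 0.06 without vehicle replicate 1, with camera adjusted p of 2.86e-10 and 0.00177, the ends of its range.

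Transcripts of antigen-presenting cells and macrophages were called downward with the preset correlation. Of 26 members 22 were below 0, with a median of -0.36 and a camera adjusted p of 7.65e-04 (adjusted p = 0.669 with an estimated correlation). At an unadjusted p under 0.05, 11 were lower, and 5 passed when adjusted over the list alone. The colony-stimulating factor receptor Csf1r differed by -0.74 (SE 0.19), the lysosomal membrane protein Laptm5 by -0.89 (SE 0.23), the class II chain H2-Eb1 by -0.47 (SE 0.14) and the brightest probe set of H2-Aa by -0.58 (SE 0.14). Without vehicle replicate 2, the array that stood apart, the median was -0.23 (camera adjusted p = 0.00348), and it ranged from -0.45 to -0.23. Of 23 T and B lymphocyte markers 18 were below 0 with a median of -0.15, which did not pass (camera adjusted p = 0.0875), and 0 passed when adjusted over the list alone. That median lay at the 30.8 percentile of random lists matched on mean expression. Gzmb, a granule protease of cytotoxic lymphocytes, and Cd3e, part of the T cell receptor complex, differed by -0.47 (SE 0.11) and -0.36 (SE 0.12). The lymphocyte list was called with genes of a mean of at least log2 6 only (adjusted p = 0.0434), without vehicle replicate 2 (adjusted p = 0.0111), without OSU-CG5 replicate 2 (0.0489) and without OSU-CG5 replicate 3 (0.0402), and fry's test for change in either direction gave it an adjusted p of 1.57e-04. With all arrays its adjusted p was 0.669 with an estimated correlation and 0.189 in fry's directional test, and its median ranged from -0.26 to -0.05.

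Stromal and muscle transcripts were also called downward with the preset correlation. Among 27 fibroblast and matrix genes 24 were below 0, with a median of -0.32 and a camera adjusted p of 8.69e-04 (adjusted p = 0.669 with an estimated correlation). Of these 10 were lower and 1 higher at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. Col5a1 differed by -0.43 (SE 0.12), the proteoglycan Bgn by -0.48 (SE 0.13) and the microfibril protein Mfap4 by -0.40 (SE 0.12). The 19 smooth muscle genes had a median of -0.27, with 17 below 0 and a camera adjusted p of 0.00910 (adjusted p = 0.739 with an estimated correlation). Of these 7 were lower at an unadjusted p under 0.05 and 1 passed when adjusted over the list alone, and examples were Lmod1 at -0.57 (SE 0.12), Smtn at -0.58 (SE 0.15), Tpm2 at -0.47 (SE 0.14) and Cnn1 at -0.40 (SE 0.14). The smooth muscle call was lost without OSU-CG5 replicate 3 (adjusted p = 0.0613) and without vehicle replicate 3 (adjusted p = 0.0960). All 22 skeletal muscle genes were below 0, with a median of -0.49, a camera adjusted p of 6.75e-07 (adjusted p = 0.669 with an estimated correlation), 14 lower at an unadjusted p under 0.05 and 9 past the threshold when adjusted over the list alone. Myh1, a fast myosin, read 5.47 ± 0.38 in vehicle and 4.09 ± 0.67 with OSU-CG5 (log2, SD, n = 3). Mb, Ryr1 and Ttn differed by -0.62, -0.59 and -0.73, and the other probe set of Mb by 0.06. The mean signal of the skeletal muscle list was low, from 4.78 to 5.74 over the arrays. With genes of a mean of at least log2 6 only, its median was -0.63 and its camera adjusted p 0.00658. The medians ranged from -0.37 to -0.25 for fibroblasts and matrix, -0.36 to -0.19 for smooth muscle and -0.63 to -0.39 for skeletal muscle.

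All 19 endothelial genes were below 0, with a median of -0.30 and a camera adjusted p of 1.29e-04 (adjusted p = 0.669 with an estimated correlation). The median ranged from -0.40 to -0.23. Of these 19, 7 were lower at an unadjusted p under 0.05 and 4 passed when adjusted over the list alone. The list's mean signal was low, from 5.13 to 5.74 over the arrays. With genes of a mean of at least log2 6 only, the median was -0.36 and the camera adjusted p 0.00658. The vessel genes Sox18, Egfl7, Plvap and Eng differed by -0.50 (SE 0.13), -0.55 (SE 0.15), -0.41 (SE 0.12) and -0.44 (SE 0.13). Immediate early genes, which respond within minutes to stimuli and handling, were called downward as a list with the preset correlation. Of 20 members 19 were below 0, with a median of -0.28 and a camera adjusted p of 0.00216 (adjusted p = 0.669 with an estimated correlation). Of these 6 were lower at an unadjusted p under 0.05 and 1 passed when adjusted over the list alone. Fosb, near the bottom of the scale at 3.55 ± 0.09 in vehicle and 3.02 ± 0.08 with OSU-CG5, differed by -0.53 (SE 0.11), Klf6 by -0.34, Jund by -0.40 and Ccn1 by -0.48, while the other probe set of Ccn1 differed by 0.04. Without vehicle replicate 2 the median of the immediate early genes was -0.15 (camera adjusted p = 0.0442), and without vehicle replicate 3 it was -0.34.

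**Figure D2:**
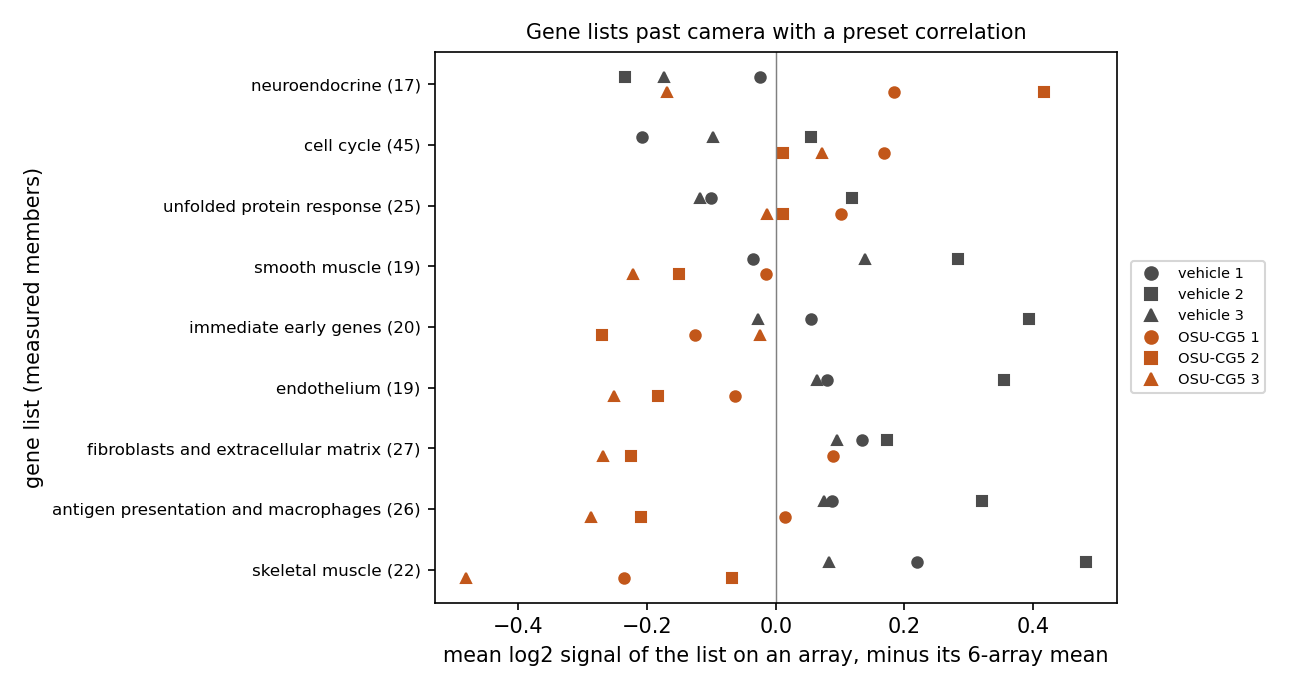
Mean log2 signal of each of the 9 gene lists past camera with a preset correlation, per array and minus the list's mean over the 6 arrays (horizontal axis), with the lists and their measured members on the vertical axis and a point per array, shaped by replicate and coloured by group. The 22 skeletal muscle genes read lower on every OSU-CG5 array than on every vehicle array, and the 45 cell cycle genes reach 8.06 in vehicle replicate 2 against 7.80 and 7.91 in the other vehicle arrays.

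The unfolded protein response list was called upward with a small shift. Its 25 members had a median of 0.04, 16 were above 0, and camera gave an adjusted p of 0.0161 (adjusted p = 0.741 with an estimated correlation). At an unadjusted p under 0.05, 3 were higher and 0 lower, and 0 passed when adjusted over the list alone. The endoplasmic reticulum co-chaperone Dnajc3 differed by 0.44 (SE 0.12), the stress sensor Atf6 by 0.36 (SE 0.11), Sel1l by 0.30 (SE 0.13) and Hsp90b1 by 0.30 (SE 0.18). The chaperone Hspa5 differed by 0.16 (SE 0.12) and the stress-induced factor Ddit3 by -0.04 (SE 0.16). The call was lost without OSU-CG5 replicate 1, vehicle replicate 1 or vehicle replicate 3 (camera adjusted p = 0.0923, 0.164 and 0.125), the median then turning to -0.01, -0.02 and -0.01, and without vehicle replicate 2 the median was 0.16 (camera adjusted p = 8.09e-04). It was also lost with cyclic loess (adjusted p = 0.185), with genes of a mean of at least log2 6 only (0.208) and with all probe sets of a gene averaged (0.114). Neuroendocrine transcripts were called upward as well, with 12 of 17 above 0, a median of 0.16 and a camera adjusted p of 0.00857 (adjusted p = 0.669 with an estimated correlation). Of these 4 were higher at an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. The 4 were Snap25, a membrane protein of synaptic vesicle fusion, and Scg5, Scg2 and Chgb, proteins of secretory granules. They varied widely among treated mice, and Snap25 read 2.78 ± 0.20 in vehicle and 4.46 ± 1.19 with OSU-CG5 (log2, SD, n = 3). The neuroendocrine call was lost without OSU-CG5 replicate 2 (adjusted p = 0.0932, median 0.07) and without vehicle replicate 2 (adjusted p = 0.140, median 0.09), and with cyclic loess the median was 0.22.

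Lists tied to energy supply and androgen action did not pass. AMPK and energy sensing had a median of 0.08 (camera adjusted p = 0.0964), which was 0.11 without vehicle replicate 2, 0.01 without vehicle replicate 3 and no longer above 0 without vehicle replicate 1. In it the kinase subunit Prkaa2 differed by 0.50 (SE 0.14), the upstream kinase Stk11 by -0.54 (SE 0.17) and the coactivator Ppargc1a by 0.43 (SE 0.16). Insulin, IGF and PI3K signalling had a median of 0.05 (camera adjusted p = 0.129), with Insr at 0.40 (SE 0.11), Pik3ca at 0.54 (SE 0.16), Igfbp5 at -0.41 (SE 0.13) and Igfbp4 at -0.67 (SE 0.24). The brightest other probe set of Insr differed by -0.40. That list was called without vehicle replicate 2 (median 0.15, adjusted p = 0.0111) and without OSU-CG5 replicate 2 (median 0.11, adjusted p = 0.0489). Its median was -0.01 without vehicle replicate 1, -0.07 without vehicle replicate 3 and -0.06 with all probe sets of a gene averaged, and with all arrays and an estimated correlation its adjusted p was 0.742. Igf1r and Igf1 differed by 0.08 (SE 0.12) and -0.21 (SE 0.38), and Txnip, a glucose-responsive gene, by 0.18 (SE 0.27). Androgen-regulated prostate genes had a median of -0.03 (camera adjusted p = 0.884), with the probasin gene Pbsn at 0.18 (SE 0.17) and Psca at -0.64 (SE 0.17), and the median ranged from -0.11 to 0.07, the upper end without OSU-CG5 replicate 2. Glycolysis had a median of -0.14 (camera adjusted p = 0.451), with Aldoa at -0.57 (SE 0.14), and the median was 0.02 without vehicle replicate 2 and -0.22 without vehicle replicate 3. Fatty acid oxidation and PPAR targets had a median of -0.12 (camera adjusted p = 0.413), with Acaa1a at -0.45 (SE 0.13), and fatty acid and cholesterol synthesis -0.09 (camera adjusted p = 0.896), with Srebf2 at -0.40 (SE 0.14). Autophagy and lysosome had a median of -0.01 (camera adjusted p = 0.745), with the lysosomal regulator Tfeb at -0.54 (SE 0.14), and oxidative phosphorylation -0.04 (camera adjusted p = 0.520), with Ndufs1 at 0.33 (SE 0.13). The fatty acid oxidation median was -0.22 without OSU-CG5 replicate 1 (camera adjusted p = 0.0520) and -0.08 without vehicle replicate 2, and the fatty acid synthesis median was -0.13 without vehicle replicate 1 and -0.02 without vehicle replicate 2. Without OSU-CG5 replicate 1 the autophagy median was -0.12 and the oxidative phosphorylation median -0.11. The autophagy median was 0.0044 without OSU-CG5 replicate 2 and also just above 0 without vehicle replicate 2, where that of oxidative phosphorylation was -0.0041.

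Stress and signalling lists did not pass either. Amino acid response genes had a median of -0.18 (camera adjusted p = 0.266), with Atf5 at -0.45 (SE 0.12), and NRF2 targets -0.18 (camera adjusted p = 0.231), with Gclc, which makes glutathione, at 0.56 (SE 0.15) and Gstm3 at -0.53 (SE 0.15). The p53 and apoptosis list had a median of -0.09 (camera adjusted p = 0.745), with Mdm2 at 0.52 (SE 0.12) and its other probe set at -0.01. Glucocorticoid-responsive genes had a median of -0.16 (camera adjusted p = 0.974), with Sgk1 at 0.34 (SE 0.12), and circadian clock genes 0.01 (camera adjusted p = 0.520), with Dbp at -0.62 (SE 0.20). The interferon response had a median of 0.02 (camera adjusted p = 0.556), with Ifit2 at 0.41 (SE 0.15). Without vehicle replicate 2 the medians were -0.10 for amino acid response and NRF2 targets, -0.0041 for p53 and apoptosis, -0.03 for glucocorticoid-responsive genes and 0.11 for the clock. The other ends of their ranges were -0.27, -0.22, -0.14, -0.19 and -0.09. The clock median lay below 0 without OSU-CG5 replicate 1 or 3 or vehicle replicate 1 or 3, and at -0.02 with all probe sets averaged. The interferon median lay below 0 without OSU-CG5 replicate 2 or 3 or vehicle replicate 1, down to -0.07, with cyclic loess at -0.01 and with all probe sets averaged at -0.10. In these lists 0 members passed when adjusted over the list alone, and the same held for the energy and androgen lists. Camera's direction was up, against negative medians and means, for the androgen, autophagy, fatty acid synthesis, oxidative phosphorylation, p53 and glucocorticoid lists. It was also up for the clock and interferon lists, with a mean below 0, and for nerve, with a median below 0 and a mean of 0.04.

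Among the remaining cell type lists, luminal epithelium had a median of -0.14 (camera adjusted p = 0.451), with Cldn3 at -0.44 (SE 0.17) and Krt8 at -0.50 (SE 0.22), and the median was 0.04 without vehicle replicate 2 and -0.22 without vehicle replicate 3. Basal epithelium had a median of -0.20 (camera adjusted p = 0.163), with Krt14 at -0.35 (SE 0.11), and was called without OSU-CG5 replicate 1 (adjusted p = 0.0443), with a range of -0.28 to -0.13. Granulocytes and acute inflammation had a median of -0.12 (camera adjusted p = 0.283), with Saa2 at -0.49 (SE 0.15), and adipocytes -0.12 (camera adjusted p = 0.225), with Pparg at -0.43 (SE 0.13). Both medians reached -0.33 with genes of a mean of at least log2 6 only, and were -0.03 and -0.04 with cyclic loess. The adipocyte median was also -0.25 and -0.23 without OSU-CG5 replicates 1 and 2. Nerve and Schwann cell genes had a median of -0.08 (camera adjusted p = 0.884), with Cnp at -0.59 (SE 0.16) and the neurofilament gene Nefl at 1.25 (SE 0.52), and the median was 0.02 without OSU-CG5 replicate 1, 0.01 with cyclic loess and -0.18 with genes of a mean of at least log2 6 only. Urothelium had a median of -0.23 (camera adjusted p = 0.138), with Upk2 at -0.46 (SE 0.11), the 1 cell type member among these that passed when adjusted over the list alone. Blood had a median of -0.24 (camera adjusted p = 0.129), with Hbb-b2 at -0.57 (SE 0.18), and the median was -0.43 without vehicle replicate 1 and -0.16 with cyclic loess. The urothelium median ranged from -0.29 to -0.14. The urothelium and blood lists were called without vehicle replicate 2 (adjusted p = 0.0442 and 0.0220), and urothelium also without OSU-CG5 replicate 3 (adjusted p = 0.0452). The 6 seminal vesicle transcripts had a median of -1.56 (camera adjusted p = 0.0629), which was -0.39 without vehicle replicate 2 (adjusted p = 0.287) and -2.42 without vehicle replicate 1 (adjusted p = 6.54e-04). This list was also called with arrays centred on their median (adjusted p = 0.0493) and with cyclic loess (adjusted p = 0.0487). All these calls used the preset correlation. With all arrays and an estimated correlation the adjusted p was 0.742 for the seminal vesicle and basal lists and 0.669 for urothelium and blood.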

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

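The test over probe sets with a single symbol was chosen after seeing the data, and the other alternatives were planned. With limma and Benjamini-Hochberg adjustment the count of probe sets was 0 under every alternative except array weights (822, of which 762 higher and 60 lower) and leave-one-out, where it ran from 0 to 885 (higher 0 to 851, lower 0 to 34), with 400 without vehicle replicate 2 and 885 without vehicle replicate 3. Of those 400 and 885, 244 were shared in direction, and 309 and 518 were shared with array weights. The unadjusted count of 1420 was 722 with a mean of at least log2 6, 264 without moderation, 233 with 1 probe set per gene and 721 with a single symbol only, all on fewer probe sets except the unmoderated fit, and 747 to 3019 with each array left out. Its lower part, 100 of 1420, was 61 of 233 with 1 probe set per gene, 216 of 1337 with repeated quantile normalization, 249 of 1010 without OSU-CG5 replicate 1 and 213 of 1163 without vehicle replicate 1. Of 9 lists called by camera, 0 were called with an estimated correlation and 0 by fry's directional test, and leave-one-out gave 7 to 12. The unfolded protein response median was 0.00 (-0.0029) under cyclic loess, where the call was lost (adjusted p = 0.185), and -0.019 to 0.164 with each array left out. With each array left out Igf1 ran from -0.616 to 0.053, Ddit3 from -0.189 to 0.084, Pbsn from -0.00961 to 0.304 and Txnip from -0.118 to 0.413, none of them past the threshold. The brightest other probe set turned the sign for Mcc (-0.018), Srcap (-0.074), Nav2 (-0.254), Ppp1r11 (0.038), Scp2 (0.082), Insr (-0.404), Mdm2 (-0.0064), Ccn1 (0.036), Mb (0.058), Igf1 (0.042), Ddit3 (0.369) and Txnip (-0.138). The cause was not tested for these changes. Of the values for single genes under the alternatives, 1280 kept their direction and side of the threshold, 69 passed it and 17 turned. No paired analysis was possible because the replicate numbers only name the mice.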

Other observations

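Families of genes sharing a symbol prefix were formed after the data were seen, so their tests were chosen only then. Of the families with at least 15 measured genes 9 passed camera, 6 upward and 3 downward, 108 did not, and 0 passed with an estimated correlation. The centrosomal Cep genes had a median log2 difference of 0.20 (37 genes, 10 higher and 2 lower at an unadjusted p under 0.05; limma camera with Benjamini-Hochberg adjustment, adjusted p = 5.40e-05, and adjusted p = 0.489 with an estimated correlation). The Ddx RNA helicases had a median of 0.09 (35 genes, 10 higher and 0 lower; adjusted p = 1.14e-04, and adjusted p = 0.659 with an estimated correlation). Cytochrome P450 genes of the Cyp family had a median of -0.16 (73 genes, 0 higher and 15 lower; adjusted p = 0.0366, and adjusted p = 0.921 with an estimated correlation). The C-type lectins (Clec) and semaphorins (Sema) had medians of -0.16 and -0.21 (adjusted p = 0.0370 for both, and 0.875 and 0.807 with an estimated correlation). Mean signal was low for the Cyp and Clec genes, at 4.78 and 4.82, and was 6.39 for Sema. Over all genes the median log2 difference was -0.09, and a trend with expression level was not tested for these families. The Rbm, Usp and Akap families were called upward with medians of 0.04, 0.02 and 0.09 (adjusted p = 0.00463, 0.0257 and 0.0305, and 0.659, 0.807 and 0.807 with an estimated correlation), and without vehicle replicate 2 the medians were 0.10, 0.09 and 0.25. The Zfp zinc finger genes were called upward with a median of 0.03 (adjusted p = 0.00405, and adjusted p = 0.921 with an estimated correlation) and not without vehicle replicate 2 (median -0.04, adjusted p = 0.608), where the medians were 0.15 for Cep, 0.16 for Ddx, -0.14 for Cyp and Clec and -0.19 for Sema.

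In the patterns weighed here, the test of nuclear RNA was set before its result was seen, and the tests of vehicle replicate 2, whole genes, RNA integrity, gene lists, neurons and array splits were chosen only after the results, or values close to them, were seen. Probe sets without a single symbol and with a mean of at least log2 6 read higher with OSU-CG5, and 428 of the 578 higher named probe sets past the descriptive threshold were secondary ones. Vehicle replicate 2 alone was argued against. Without it the unnamed probe sets lay 0.14 above the named ones, against 0.24 with all arrays. The interval came from another measure, not to be set against those values: the medians of single arrays, unnamed minus named. Without vehicle replicate 2 these differed between the groups by 0.27 (95% t interval over arrays 0.07 to 0.46, exact permutation p = 0.1, the smallest that 3 arrays against 2 allow). With all arrays this difference was wider, since the value was -0.54 and -0.48 in vehicle replicates 1 and 3 but -1.07 in vehicle replicate 2. A larger share of RNA retained in the nucleus may contribute but rests in part on that array: a fixed list of Malat1, Neat1, Meg3, Rian, Mirg and Airn had a median of 0.56 and a mean signal higher on each OSU-CG5 array than on each vehicle array, with Malat1 at 1.46 (SE 0.49) and Neat1 at 1.42 (SE 0.31), but Mirg at 0.00, while without vehicle replicate 2 the median was 0.24, under the 0.3 set in advance. A change of whole genes stays open: in 387 genes the brightest probe set had a median of 0.17 (95% bootstrap interval over genes 0.14 to 0.22) against 0.85 for the higher secondary ones, a ratio whose interval of 0.168 to 0.260 overlaps that of 0.206 to 0.50 for 36 genes selected in the same way as lower. RNA integrity stays open too, with Gapdh 3' to 5' signal 0.51 higher with OSU-CG5 and the groups overlapping, and so does an effect of OSU-CG5 on RNA processing, which was not tested.

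The muscle, endothelial, matrix and macrophage lists read lower together. A trend with expression level was argued against, since the 5 medians lay at or below the 0.03 percentile of matched random lists. Vehicle replicate 2 stays open as a source: without it the mean signal of the 5 lists differed by -0.26, against -0.34 with all arrays, but its 95% t interval over the remaining arrays ran from -0.57 to 0.04. The list mean was lower on each OSU-CG5 array than in vehicle replicates 1 and 3 for 4 of the 5. For fibroblasts and matrix the margin was narrow, with 7.84 in OSU-CG5 replicate 1 and 7.85 in vehicle replicate 3. The 5 lists were picked as lower on these same arrays, so this separation is no independent evidence. Without vehicle replicate 2 all 5 passed camera with the preset correlation, with medians of -0.39 to -0.19. For endothelium the mean signal then differed by -0.24 (95% t interval -0.47 to -0.01), while the intervals of the other lists included 0. Camera with the preset correlation does not settle it, since no splits of the arrays were run without vehicle replicate 2. With all arrays, 5 of the 10 splits, the real one included, reached the real count of list calls. That count was over all lists in both directions, so it does not decide about these 5. The estimated correlation decides nothing here, with 0 of the 5 lists past the threshold with all arrays and 0 without vehicle replicate 2 (adjusted p = 0.432 to 0.634). A trend with expression level could account for the unfolded protein response call, whose median lay at the 57.11 percentile. A lower share of non-epithelial tissue in the treated dissections stays open: the luminal list lay at the 0.7 percentile with all arrays and at the 51.94 percentile without vehicle replicate 2, and the adipocyte and nerve lists, with medians of -0.12 (range over the alternatives -0.33 to -0.04) and -0.08 (-0.18 to 0.02), were not called. An effect of OSU-CG5 within those cells was not tested.

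Neuroendocrine transcripts read higher, mainly Snap25, Scg5, Scg2 and Chgb. Ganglion neurons in some dissections are a candidate explanation, and 12 neuron genes outside that list had a median of 0.00 (0.00079), at the 98.76 percentile of matched random lists, with Nefl at 6.43, 5.41 and 3.96 on the OSU-CG5 arrays and 3.75 to 4.31 in vehicle. Only 2 of these 12 had a mean of at least log2 6, and Uchl1 differed by 0.06 (SE 0.16) and Th by -0.26 (SE 0.18), so the test does not decide. Neuroendocrine tumour cells stay open as well. The 6 measured members not grouped here as shared with neurons had a median of -0.10, and 2 were above 0. Chga differed by -0.18 (SE 0.13) and Ddc by 0.42 (SE 0.24). Of these 6, 0 had a mean of at least log2 6, and whether neurons also make them was not tested.

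The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. With limma, 10 of the 10 splits gave 0 adjusted calls, the highest of the others being 0. The 1420 probe sets at an unadjusted p under 0.01 and 1.5-fold were reached in 1 of 10 splits, the real one, and the highest other gave 219. For the 9 lists called by camera, 5 of 10 splits gave as many, and the highest other gave 13, in a split that put vehicle replicate 2 with OSU-CG5 replicates 1 and 3. Relative to the mean of the other vehicle arrays, vehicle replicate 2 read at least 4-fold lower for 186 probe sets and at least 4-fold higher for 13. Of those 186, 96 had no single symbol, while such probe sets made up 22.4% of those tested. The 64 Affymetrix controls gave 0 adjusted calls in limma, with a smallest adjusted p of 0.126, and 19 at an unadjusted p under 0.05, which is 29.7% of them, against 16.4% of the tested probe sets and 5% by chance.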
